A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

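The material was genomic DNA of budding yeast cut in the cell by micrococcal nuclease fused to MCM4 and read on a nanopore MinION sequencer with R9 flow cells. Per the labels' protocols, cells grew in rich medium at 30 °C, were arrested in G1, received BrdU at 400 µg/mL 30 min before release and were released at 25 °C. The time of harvest is not given in the sources used here. The 8 records are 4 libraries, each recorded once for reads and once for raw signal, and each library was counted once. Per the labels, replicates are biological replicates.

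Each deposited table holds 1 row per alignment, with contig, start, end, read name, a value per read and strand. Per the submitters' processing notes minimap2 was used, and per the series' design text BrdU reads can be selected with DNAscent; versions and genome build are not given in the sources used here. The value per read deposited by the authors is a fraction from 0 to 1, apparently the share of windows of a read called BrdU-positive, but neither window nor threshold is stated. Alignment ends are deposited as positions, to which no normalization applies. In each table, 2 or 3 rows without a position were left out. The rDNA is a separate contig and was kept out of the nuclear measures. The shortest deposited span was 250 bp.

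For each read the longest alignment was kept. Spans were taken for molecules of at least 3 kb. Positions are 1-based. No genome, origin, centromere, tRNA or repeat annotation of this build was used, so centres were called from the data. Midpoints of BrdU-positive molecules (share of at least 0.5) of 1 to 3 kb were counted in 100 bp bins, weighted equally by library and smoothed with a Gaussian of SD 1000 bp. Peaks at least 5000 bp apart were kept with a prominence of at least 0.5 of their height, 30 molecules within 1500 bp and 2 per library. Of 196 peaks, 13 were removed because at least 0.3 of their molecules shared 1 end within 200 bp, leaving 183.

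Arms were measured for molecules that span exactly 1 centre lying at least 500 bp from both ends. Asymmetry is the absolute difference of the arms over their sum, and signed balance is right minus left over the sum. Group values are mean and SD over libraries, compared with two-sided exact permutation tests over all 6 assignments. Intervals for shares are 95% Wilson intervals, and those for asymmetry come from 1000 bootstrap draws of centres. Both cover counting error within a library only. Counts per centre were fitted with limma's voom, and mean asymmetry or balance per centre with limma, after filters of a mean of 10 counts or 10 molecules in every library. The false discovery threshold was 0.05. For spanning counts, at centres and in 5 kb bins, and for BrdU-positive asymmetry limma estimated 1 variance shared by all centres or bins. The SE and p of a single centre or bin there do not reflect the spread between its own replicates. For BrdU-positive spanning counts the prior had 171 degrees of freedom, so the SE and p come almost wholly from the pooled variance. Lists were tested with camera at a preset correlation of 0.01. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.

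The tests, samples, alternatives and rule for named sites were fixed before the data were examined, and the following departs from or adds to them. The fixed design assumed annotated origins and no selection on BrdU. Called centres replaced annotated origins, and 5 kb bins were used as the fixed fallback for spanning and end counts. Restriction to BrdU-positive molecules was added after the data were seen and with knowledge of the study's subject. It is the selection the series' design text describes, and it reverses the direction of the arm comparison. The definition of centres was revised after arm asymmetry of BrdU-positive molecules had been seen. A first version called 309 centres from molecules of 2 to 8 kb without prominence, per-library or fixed-end filters and measured molecules of at least 8 kb. It gave 0.345 and 0.415 in pol2-REL and 0.280 and 0.296 in pol2-REL-exo. Molecules of 1 to 3 kb were then used so that calling and measuring sets do not overlap, and the filters were added. Lists of isolated centres (no other within 20000 bp) and of the 45 most used centres were also added.

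Sites named are, per test, those past the threshold without overlap of genotypes, up to the 5 largest and 5 smallest changes, and the 5 centres with the most single-centre molecules. The fixed rule named 5 kb bins where no origins are annotated, so bins past the threshold are named too, and naming centres by position is an addition. Lists fixed by origin name, the centromere list, ends at tRNA genes, centromeres and repeats, and the mapping quality alternative were not run, for lack of annotation or of that column.

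Replicates of a genotype shared 115 of 383437 and 489480 distinct intervals in pol2-REL and 470 of 1135537 and 807926 in pol2-REL-exo, and libraries of different genotypes shared 118 to 376, so no library was a copy of another. The methods were tested on simulated data. On simulated molecules with 99 known centres, all 99 were found within 1000 bp, and asymmetry was returned to within 0.00163. Those centres were evenly spaced, far apart and equally used, and most molecules lay on one. In the data only 130 of 183 centres had no other within 20000 bp. Of BrdU-positive molecules, 33.5 to 50.4% spanned no centre. Centres and asymmetry may therefore be returned less well in the data. On simulated counts for 183 centres with 40 changed 4-fold, spanning counts recovered 100% and end counts 97.5%. At 2-fold they recovered 55% and 30%, and BrdU-positive spanning counts 20%. With no centre changed, the spanning test made 1 false call, as many as it made on the data. BrdU-positive asymmetry made 0 false calls with no centre changed and 3 beside changes of 0.1, against 9 calls on the data. A change of 0.1 in asymmetry at 40 centres was recovered in 100% for molecules of any BrdU share and in 75% for BrdU-positive molecules at 157 centres. These simulated counts and asymmetries had independent noise per centre and library, without a shift shared by the centres of a library or genotype. The data do hold such shifts, so recovery and false calls there may differ from these values.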

Results

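Replicon-seq reads out how far replication forks have travelled on single DNA molecules. The replicative helicase subunit MCM4 is fused to micrococcal nuclease, so that DNA is cut where replisomes sit, and the freed molecules are read from end to end on a nanopore sequencer. Budding yeast cells were held in G1 with the mating pheromone alpha factor and let into S phase at 25 °C with the thymidine analogue BrdU, which marks newly made DNA. The strains carried pol2-REL or pol2-REL-exo, alleles of the gene for the catalytic subunit of DNA polymerase epsilon, the leading strand polymerase. Each genotype had 2 biological replicates, 4 libraries in all, and no wild-type library was analysed here. The series title names fork symmetry as its subject, so the main question was whether the arms on either side of an origin differ in length more in one genotype than in the other.

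The pol2-REL libraries held 796777 and 848809 aligned reads and the pol2-REL-exo libraries 2321430 and 1676071. Of these, 383477, 489907, 1136416 and 808602 were nuclear molecules with an aligned span of at least 3 kb, which entered the comparisons. A share per read between 0 and 1, deposited with each alignment, gives how much of the read carried BrdU. Molecules with a share of at least 0.5 are called BrdU-positive here. That threshold was chosen after the data were seen, and so was every result on BrdU-positive molecules. With 2 libraries against 2, the smallest two-sided p an exact permutation test can give is 0.333, so no comparison of library values could pass 0.05.

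Molecules were longer in pol2-REL. The median span was 11799 and 13078 bp in the pol2-REL libraries and 9683 and 9875 bp in the pol2-REL-exo libraries (12439 ± 904 against 9779 ± 136 bp, SD, n = 2 each, exact permutation p = 0.333). The difference of the means exceeded the spread within either genotype.

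BrdU-positive molecules were more frequent and longer in pol2-REL. They made up 4.79% (95% Wilson interval 4.73 to 4.86%) and 10.1% (10.1 to 10.2%) of molecules in pol2-REL, against 2.73% (2.70 to 2.76%) and 3.67% (3.63 to 3.71%) in pol2-REL-exo. The means were 7.47 ± 3.78% and 3.20 ± 0.663% (SD, n = 2 each, exact permutation p = 0.333), and pol2-REL replicate 2 stood apart from the other libraries. Their median span was 10994 ± 1098 bp in pol2-REL and 7647 ± 288.5 bp in pol2-REL-exo (SD, n = 2 each, exact permutation p = 0.333). Among molecules of 20 to 40 kb, 3.98% and 9.29% were BrdU-positive in pol2-REL and 1.04% and 2.19% in pol2-REL-exo. Without pol2-REL replicate 2 the difference in the positive share shrank from 4.27 to 1.59 percentage points.

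**Figure D1:**
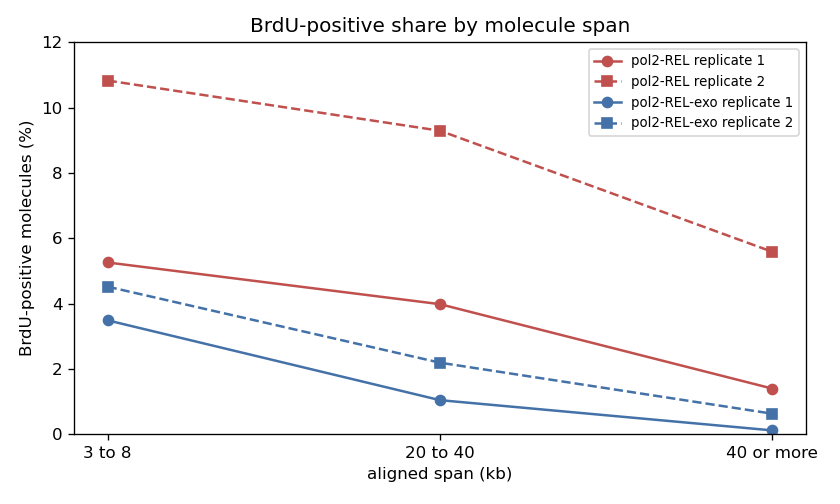
Share of BrdU-positive molecules (%, vertical axis) at aligned spans of 3 to 8, 20 to 40 and 40 or more kb (horizontal axis), 1 line per library, red for pol2-REL and blue for pol2-REL-exo. Both pol2-REL libraries lie above both pol2-REL-exo libraries in each class, at 3.98% and 9.29% against 1.04% and 2.19% for 20 to 40 kb.

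No origin annotation for the genome build of the files was used, so origins were represented by 183 replicon centres, places where midpoints of short BrdU-positive molecules of 1 to 3 kb pile up. The molecules used to call centres were not among those of at least 3 kb that were measured. The 5 centres with the most single-centre molecules, counted at any BrdU share, lay at position 799050 of chromosome 2, 408050 of chromosome 9, 1043050 of chromosome 15, 895950 of chromosome 13 and 39150 of chromosome 3. Their means were 1450 to 1286.5 molecules per library. None had another centre within 20 kb, and only 408050 was among the 45 centres with the most short BrdU-positive molecules. The genome build is not given in the sources used here.

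**Figure D2:**
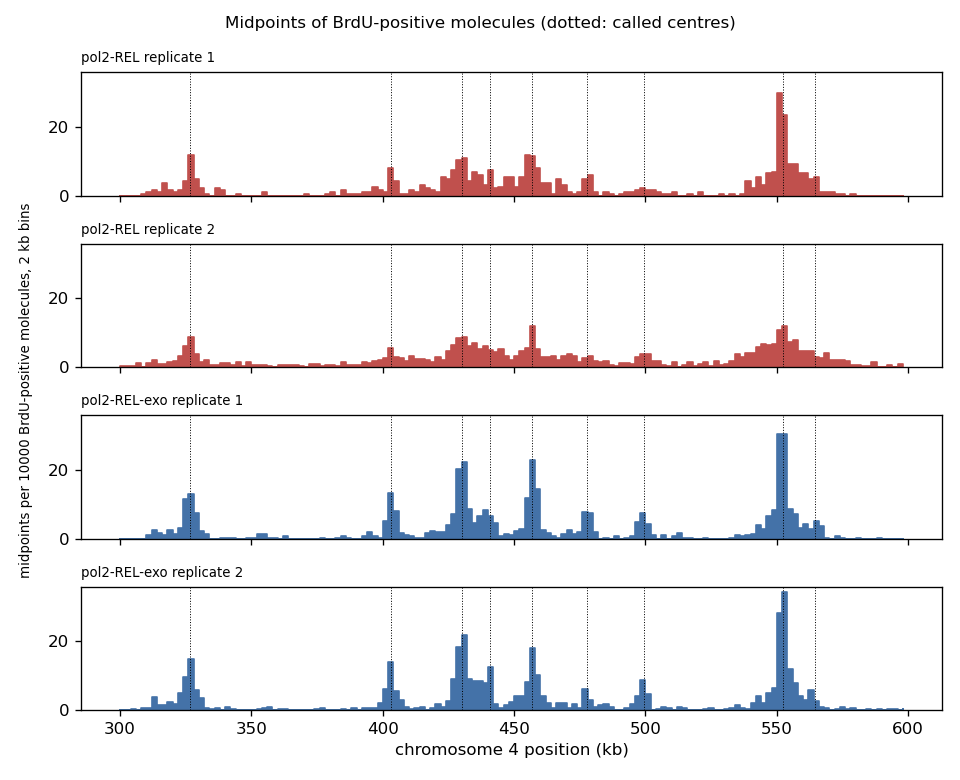
Midpoints of BrdU-positive molecules of at least 3 kb in 2 kb bins, scaled to their number in each library (vertical axis), along chromosome 4 from 300 to 600 kb (horizontal axis), 1 panel per library, with dotted lines at called centres. Peaks stand at most of the called centres in all 4 libraries.

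The direction of the difference in arm asymmetry turned on which molecules were measured. Under the definition fixed before the data were examined, which takes molecules of any BrdU share, arm asymmetry was lower in pol2-REL. This measure, the difference of the arms over their sum, was 0.434 (95% bootstrap interval over centres 0.428 to 0.439) and 0.441 (0.436 to 0.445) in pol2-REL and 0.443 (0.439 to 0.447) and 0.446 (0.442 to 0.451) in pol2-REL-exo. The means were 0.437 ± 0.00512 and 0.444 ± 0.00255 (SD, n = 2 each, exact permutation p = 0.333). The difference of 0.00730 was small, and 1 pol2-REL library lay within the interval of a pol2-REL-exo library. With all libraries and no selection on BrdU, the difference ranged from 0.00375 with the first version of the centre call to 0.0252 at the 45 most used centres. Most of these molecules carried no BrdU. A share of 0 was found in 80.6% and 70.2% of them in pol2-REL replicates 1 and 2. In pol2-REL-exo replicates 1 and 2 it was found in 86.1% and 80.2%. BrdU marks newly made DNA, and whether the ends of molecules without it lay at forks was not tested. The small difference over molecules of any BrdU share therefore does not decide whether fork arms differed in symmetry between the genotypes.

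In BrdU-positive molecules the direction was the opposite, with higher asymmetry in pol2-REL. It was 0.321 (0.316 to 0.327) and 0.373 (0.369 to 0.378) in pol2-REL, against 0.298 (0.294 to 0.301) and 0.306 (0.303 to 0.311) in pol2-REL-exo. The means were 0.347 ± 0.0367 and 0.302 ± 0.00633 (SD, n = 2 each, exact permutation p = 0.333). The difference exceeded the SD of pol2-REL but was smaller than the distance between its libraries, at 0.321 and 0.373. The median longer arm was 8750.5 and 10599 bp in pol2-REL and 5544 and 5966 bp in pol2-REL-exo, and the median shorter arm 4018.5 and 3977 bp against 2825 and 2947 bp. The longer arm was at least 4 times the shorter in 17.7% and 23.4% of BrdU-positive molecules in pol2-REL and in 11.1% and 12.2% in pol2-REL-exo. The genotypes were close among molecules of 3 to 8 kb, at 0.344 ± 0.00235 and 0.332 ± 0.000299, and apart at 8 to 16 kb, at 0.390 ± 0.0394 and 0.294 ± 0.0108 (SD, n = 2 each). Molecules with a BrdU share of 0 had values of 0.451, 0.455, 0.460 and 0.464 in the same order. Asymmetry of BrdU-positive molecules followed the BrdU-positive share of all molecules in rank over the 4 libraries. Among single-centre molecules that share was 11.8%, 18.4%, 10.1% and 11.9%. There the rank differed only between pol2-REL replicate 1 and pol2-REL-exo replicate 2, whose shares were nearly equal. Without pol2-REL replicate 2 the difference fell from 0.0454 to 0.0195. The measured molecules were a smaller part of the BrdU-positive ones in pol2-REL. Exactly 1 centre was spanned by 52.8% and 44.6% of them in pol2-REL and by 64.2% and 60.9% in pol2-REL-exo. No centre was spanned by 42.8% and 50.4% against 33.5% and 36.2%. Whether molecules not centred on a called centre raised the asymmetry in pol2-REL was not tested.

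**Figure D3:**
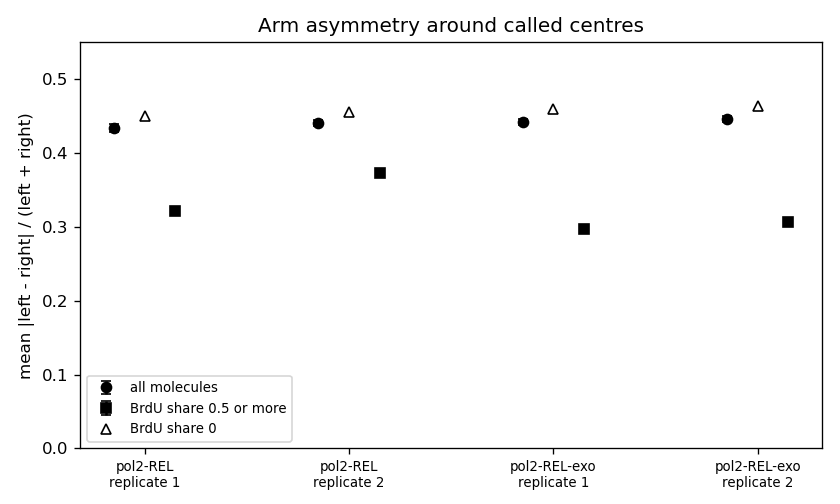
Mean arm asymmetry (no unit, vertical axis) in each library (horizontal axis) for all molecules (circles), BrdU-positive molecules (squares) and molecules with a BrdU share of 0 (triangles), with 95% bootstrap intervals over centres for the first pair of classes. BrdU-positive molecules give 0.321 and 0.373 in pol2-REL and 0.298 and 0.306 in pol2-REL-exo, while all molecules give 0.434 to 0.446 with the opposite order of genotypes.

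Molecule ends lay at centres more often in pol2-REL-exo. Within 500 bp of a centre lay 2.30% and 2.25% of all ends in pol2-REL and 2.58% and 2.64% in pol2-REL-exo (2.28 ± 0.0361% against 2.61 ± 0.0431%, SD, n = 2 each, exact permutation p = 0.333). These windows cover 1.51% of the nuclear genome, so ends were 1.53, 1.49, 1.71 and 1.75 times as dense there as over the genome. The difference was larger than the spread within either genotype.

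At single centres, limma with Benjamini-Hochberg adjustment found few differences in molecules of any BrdU share when all libraries were used without a replicate block. With the replicate number as a block, 166 of 183 centres were called lower in spanning count. Without the block, 178 of 183 centres had a negative log2 change in pol2-REL-exo. Library size was the number of molecules whatever their length, and molecules were longer in pol2-REL. Such a shared shift therefore cannot be told apart from a difference in molecule length. Only 1 centre passed the threshold, at position 368050 of chromosome 13, where the log2 change was -0.88 ± 0.23 (SE, limma adjusted p = 0.0198). The call was lost when library size was set by the median ratio over centres, which removes a median shift of -0.29 on the log2 scale, and also, at changes of -0.85, -0.74 and -0.98, with spans from 1 kb and without pol2-REL-exo replicate 1 or 2. Without pol2-REL replicate 1 the change was -0.49, and 158 of 183 centres were called lower. No centre changed in arm asymmetry or in signed arm balance by limma, with 14 and 31 centres at an unadjusted p under 0.05. End counts passed the threshold as higher in pol2-REL-exo at 15 centres and as lower at 0. The largest log2 changes were 0.63 ± 0.12 at position 695550 of chromosome 10, 0.62 ± 0.15 at 597750 of chromosome 12, 0.59 ± 0.13 at 73850 of chromosome 3, 0.58 ± 0.12 at 274550 of chromosome 15 and 0.55 ± 0.13 at 468450 of chromosome 5 (SE, limma adjusted p = 0.0460 each). The median centre moved by 0.19, and relative to that shift, with the median ratio as library size, 0 centres were called, with 21 at an unadjusted p under 0.05 by limma. Without either pol2-REL-exo library 0 centres were called, the named ones included (limma adjusted p = 0.0922 to 0.172, with 41 and 50 centres at an unadjusted p under 0.05), and 35 rose without pol2-REL replicate 2. Position 468450 of chromosome 5 was the least stable, lost under 7 of 9 alternatives and at 0.27 without pol2-REL replicate 2.

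The same limma models on BrdU-positive molecules called 4 centres with more and 5 with fewer spanning molecules in pol2-REL-exo. The clearest was position 566250 of chromosome 14, at -1.41 ± 0.24 (SE, limma adjusted p = 2.2e-06), which passed under all 9 alternatives tried for it. The SE and p in this test come almost wholly from a variance pooled over centres. Positions 215550 of chromosome 6 and 617150 of chromosome 12 fell by 1.89 ± 0.45 and 1.84 ± 0.45 (limma adjusted p = 0.00412 each). Positions 564450 of chromosome 4 and 344350 of chromosome 15 had changes of -0.85 and -0.80. The calls at 215550, 617150 and 344350 were lost without either pol2-REL-exo library, and those at 564450 and 344350 without pol2-REL replicate 2. In all, 344350 lost its call under 6 of 9 alternatives, and 564450, 215550 and 617150 under 2 of 9 each. All 5 that fell had another centre within 20 kb, 9800 to 19400 bp away, and the 4 that rose had none. Over all centres, 130 of 183 had none. With a preset correlation, camera placed those 130 above the other centres (adjusted p = 0.00102), a call lost with an estimated correlation (adjusted p = 0.278). At 566250 only 20, 53, 13 and 15 of 83, 201, 47 and 50 BrdU-positive spanning molecules crossed no other centre. The 4 that rose were 899050 of chromosome 15 by 0.73, 26150 of chromosome 13 by 0.64, 402850 of chromosome 2 by 0.62 and 895950 of chromosome 13 by 0.61. These rises include a median shift of 0.17, and with the median ratio as library size 0 centres rose and 4 fell. Without pol2-REL replicate 2 the rises at 402850, 26150 and 895950 were 0.25, 0.41 and 0.37, that at 899050 was 0.95, and the calls were lost. Without pol2-REL-exo replicate 2 the rises were 0.57 at 899050, 0.68 at 26150 and 0.54 at 402850 and 895950, again without calls. The balance of directions was not stable, at 11 up and 358 down in 5 kb bins, 2 up and 41 down with the first centre call and 54 up and 14 down without pol2-REL replicate 1.

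Arm asymmetry of BrdU-positive molecules was lower in pol2-REL-exo at 141 of 157 centres, of which 9 passed the limma threshold, all lower. The largest differences were -0.212 ± 0.0381 at position 124050 of chromosome 1 (SE, limma adjusted p = 9.2e-06), -0.180 ± 0.0381 at 238850 of chromosome 10, -0.154 at 617150 of chromosome 12, -0.136 at 104250 of chromosome 6 and -0.126 at 109450 of chromosome 8. In that order, the library with the fewest molecules had 13, 10, 12, 10 and 30, against a filter of 10. With at least 30 molecules in every library, 1 of 107 centres passed, as lower. With a BrdU threshold of 0.3 or of 0.7 in place of 0.5, 0 centres passed in limma, with 25 and 17 at an unadjusted p under 0.05, although the median difference stayed at -0.0459 and -0.0402. Without pol2-REL replicate 2, 113 of 157 centres were lower, the median difference moved from -0.0456 to -0.0204, and 17 centres passed as lower and 3 as higher. The difference at 617150 was then -0.0863, and each named position lost its call without pol2-REL-exo replicate 2, and all but 124050 also without replicate 1. Signed arm balance changed at 0 of 157 centres by limma, with 15 at an unadjusted p under 0.05.

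The list of subtelomeric centres, within 25 kb of a chromosome end, had only 3 members, of which 0 changed alone in any test on molecules of any BrdU share, over all centres or adjusted over the list alone. With a preset correlation, camera placed it above other centres in spanning count (adjusted p = 1.2e-05), with a median log2 change of 0.0011 against -0.29 elsewhere. That call was lost with an estimated correlation (adjusted p = 0.322). Its adjusted p was 0.448 for arm asymmetry, 0.628 for signed balance and 0.479 for end counts.

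The rule fixed in advance named 5 kb bins for the case of no origin annotation, and counting in them showed a bin of chromosome 5, from 130001 to 135000, nearly empty in both pol2-REL-exo libraries. Spanning molecules numbered 173 and 240 there in pol2-REL and 2 and 2 in pol2-REL-exo, a log2 change of -7.50 ± 0.29 (SE, limma adjusted p = 5.4e-131). The bins on either side, from 125001 to 130000 and 135001 to 140000, were empty in pol2-REL-exo replicate 2 alone, with 284 and 272 molecules in replicate 1. Their log2 changes of -4.93 and -5.07 therefore rest on that replicate. In pol2-REL-exo, molecules of any BrdU share were nearly missing from the middle bin. At 15 kb to its left and right lay 1205 and 1213 molecules in replicate 1 and 824 and 869 in replicate 2. Coverage also dipped in pol2-REL, with 187 molecules over the bin midpoint against 448 and 436 on these sides in replicate 1. In pol2-REL replicate 2 the numbers were 253 against 699 and 623. Whether the DNA itself is absent from the pol2-REL-exo strains was not tested, so the change is not read as one in replication. The middle bin also had fewer molecule ends, by a log2 change of -5.46 ± 0.65 (limma adjusted p = 0.00276). Bins on chromosome 13 from 360001 to 365000 and 365001 to 370000 changed by -0.82 and -0.86, and the bin on chromosome 10 from 750001 to 755000 by 0.87. In all, 7 of 2404 bins changed in spanning count and 1 of 2406 in end count.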

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

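All tests weighed in this part were chosen after the results were seen.

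Molecules on the rDNA contig lie outside the comparisons. Of rDNA molecules of at least 3 kb, 4.48% and 4.80% were BrdU-positive in pol2-REL and 3.02% and 2.46% in pol2-REL-exo. The right ends of BrdU-positive rDNA molecules gathered between positions 7201 and 7800 of the 9001 bp contig, with 33.9% and 31.2% of them in pol2-REL and 44.5% and 36.1% in pol2-REL-exo. Among rDNA molecules with a BrdU share of 0 the mean was 7.26% in pol2-REL and 6.69% in pol2-REL-exo.

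BrdU-positive molecules with fixed ends were found at a pair of loci removed from the centres. On chromosome 9, 197 ran from 203444 to 208840, and on chromosome 4, 110 ran from 1086993 to 1092374, lengths of 5397 and 5382 bp. Most came from the libraries numbered 2, with 64 against 7 in pol2-REL on chromosome 9 and 36 and 58 against 5 and 11 on chromosome 4.

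For the molecules with fixed ends, an alignment break against the reference would end molecules alike whatever their BrdU share. With libraries pooled, BrdU-positive molecules ended there 5.04 times as often as those with a share of 0 on chromosome 9. In single libraries this was 2.64 to 8.74 times. On chromosome 4 it was 10.9 times with libraries pooled and 5.66 to 17.4 times in single libraries. Of BrdU-positive molecules overlapping that place, 66.2% on chromosome 9 and 87.4% on chromosome 4 ended there. At a share of 0 this was 13.1% and 8.01%. The loci were picked as the commonest pairs of ends among BrdU-positive molecules, which favours a ratio above 1. The loci ranked 3 to 6 by the same rule gave ratios of 2.04 to 7.62, with 7.21 to 23.3% of BrdU-positive molecules ending there. Chromosome 4 lay above that range and chromosome 9 within it. Because the rule favours high values, the ratio alone does not decide about an alignment break. Reverse-transcribed DNA of a retrotransposon remains a candidate source: both loci have nearly the same length, and with libraries pooled 78.8% of partial molecules on chromosome 4 were read from the fixed end. The locus ranked 4, on chromosome 12, gave 75% at another length, 5173 bp. Those ranked 3, 5 and 6 gave 47.1 to 52.8%. Pheromone is known to induce the yeast element Ty3. No repeat annotation was used, so this is a hypothesis, and the strand test does not identify the element.

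The higher arm asymmetry of BrdU-positive molecules in pol2-REL is the second pattern. A difference in molecule length is argued against, since weighting to a common span distribution left 0.0623. More breakage of all DNA in pol2-REL is argued against by molecules with a BrdU share of 0, which were longer there by 2706 bp. More S phase progress at harvest cannot be told apart from genotype: the libraries closest in BrdU-positive share, pol2-REL replicate 1 and pol2-REL-exo replicate 2, differed by only 0.0150. The genotype itself stays open, untested. The pattern is absent from molecules of any BrdU share, most of which carried no BrdU.

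The longer BrdU-positive molecules in pol2-REL are the third. Longer fragments in the whole library are argued against as the only cause, because the positive share at 20 to 40 kb over that at 3 to 8 kb was higher in pol2-REL by 0.416. More S phase progress at harvest cannot be told apart from genotype, since BrdU-positive molecules were also more frequent by 4.27 percentage points and the harvest time is not given in the sources used here.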

How the results depend on the processing

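BrdU thresholds, other centre calls, kept fixed-end centres, the isolated and most used lists and all results on BrdU-positive molecules were chosen after the data were seen, and the other alternatives before. The rule fixed before named 5 kb bins where origins are not annotated, and called centres were put in their place after the data were seen. Arm asymmetry (pol2-REL-exo minus pol2-REL) reversed from 0.00730 to -0.0454 when restricted to a BrdU share of at least 0.5, and kept its sign under its 21 other alternatives, at 0.00480 with a margin of 1500 bp from the ends, 0.00375 with the first centre call, 0.00403 with the mean over centres, 0.0121 with centres from pol2-REL alone, 0.0111 with spans matched and 0.0252 at the most used centres. In the first 3 of these and with spans from 1 kb, single libraries of the genotypes overlapped. Median length, ends at centres and the BrdU-positive length, share and asymmetry kept their direction under every alternative run. Leaving out single libraries gave 0.00368 to 0.0109 for asymmetry, -0.0713 to -0.0195 for BrdU-positive asymmetry, -3299 to -2020 bp for length, -4123.5 to -2570.5 bp for BrdU-positive length, -6.94 to -1.59 percentage points for the BrdU-positive share and 0.304 to 0.365 for ends. The cause of the moved counts below was not tested.

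Counts of centres depended strongly on settings. Leaving out single libraries gave 0 to 158 for spanning counts (main 1), 0 to 8 for asymmetry (main 0), 0 to 3 for balance (main 0), 0 to 36 for ends (main 15), and for BrdU-positive molecules 3 to 68 for spanning (main 9), 0 to 46 for asymmetry (main 9) and 0 to 0 for balance (main 0). The 158 arose without pol2-REL replicate 1, and 1 was called without pol2-REL replicate 2. Spanning counts gave 0 with spans from 1 kb, 0 with the median ratio, 7 in 5 kb bins and 9 at a BrdU share of at least 0.5. Asymmetry gave 2 weighted and 9 at that share. Balance gave 20 with spans from 1 kb and 6 with centres from 2 to 8 kb molecules. Ends gave 4 with spans from 5 kb, 30 with centres from 2 to 8 kb molecules, 0 with fixed-end centres kept, 0 with the first centre call, 0 with the median ratio, 1 in 5 kb bins and 31 for a BrdU share of 0. BrdU-positive spanning gave 4 with spans from 5 kb, 5 with centres from 2 to 8 kb molecules, 5 with fixed-end centres kept, 43 with the first centre call (2 up, 41 down), 4 with the median ratio, 369 in 5 kb bins (11 up, 358 down) and 4 at a share of 0.3. BrdU-positive asymmetry gave 3 and 0 with spans from 5 and 1 kb, 14 with centres from 2 to 8 kb molecules, 1 with at least 30 molecules, 15 weighted and 0 at shares of 0.3 and 0.7. Spans from 1 kb overlap the molecules that called the centres. All 172 repeats for named sites kept their direction, and 73 no longer passed.

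With the replicate number as a block, position 368050 of chromosome 13 moved from -0.88 to -0.50 in spanning count (limma adjusted p = 0.0572). Centres called with the block were 166 for spanning, 3 for asymmetry, 13 for balance and 4 for ends, and 8, 14 and 6 for BrdU-positive spanning, asymmetry and balance; paired differences of single values equal the unpaired ones, at -2659.5 bp, -3347 bp, -4.27, 0.335, -0.0454 and 0.00730. Same-numbered libraries correlated across centres at 0.153, 0.0689, -0.0599 and 0.00724 in the main tests. Some library values went with the number. The BrdU-positive share was higher in replicate 2, at 10.1% against 4.79% in pol2-REL and 3.67% against 2.73% in pol2-REL-exo. Full-length fixed-end BrdU-positive molecules on chromosome 4 numbered 36 and 58 in replicate 2 of pol2-REL and pol2-REL-exo, against 5 and 11. The share of ends at centres did not go with it, being lower in replicate 2 of pol2-REL and higher in that of pol2-REL-exo. With only 2 pairs, these values do not settle whether same-numbered libraries share more than a number. Under camera, an estimated correlation ended the calls for subtelomeric spanning (adjusted p = 0.322), for isolated and most used centres in asymmetry (0.444 each), ends (0.432 and 0.645) and BrdU-positive spanning (0.278 and 0.557). Mapping quality, feature classes and lists by origin name were not run.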

Other observations

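All measurements in this part were chosen after the data were seen.

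The gap on chromosome 5 in pol2-REL-exo had different borders in its replicates, and whether DNA is missing from these strains was not tested. Molecules over the midpoint of the bin from 130001 to 135000 numbered 187 and 253 in pol2-REL and 4 and 2 in pol2-REL-exo. In pol2-REL-exo replicate 1 the commonest right end lay at 129701 and the commonest left end at 135201. In replicate 2 they lay at 123001 and 141901. In both pol2-REL libraries the commonest right end lay at 136401 and the commonest left end at 128501.

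From the strand of each read, taken as the new strand, the arm made as leading strand was longer than the arm made as lagging strand in molecules with partial BrdU. As a share of the span, the mean difference for a BrdU share of 0.3 to 0.5 was 0.0735 ± 0.00868 and 0.0769 ± 0.00583 in pol2-REL and 0.0782 ± 0.00759 and 0.120 ± 0.00650 in pol2-REL-exo (SE across molecules, which are not replicates). At positions moved by 15 kb the same class gave -0.0375, -0.00592, -0.0424 and -0.0605, so this control was not at 0. At a share of 0.7 or more it was 0.0201, 0.00602, 0.0174 and 0.0162 in the same order. Under the same assignment, molecules with a BrdU share of 0 had the opposite sign, at -0.0303, -0.0359, -0.0232 and -0.0287. At positions moved by 15 kb they gave 0.00337, 0.00530, -0.00346 and 0.000715. Without BrdU, nothing shows that the read is the new strand, so for these molecules the sign does not tell which arm was longer.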
